A study of Mus musculus with 26 samples.

How the data were processed

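The study measured RNA in 26 libraries of mouse thymocytes from C57BL/6 animals of 6 to 8 weeks. DN1eP precursors (4 libraries) were sorted as lineage-negative, CD44-positive, CD25-negative cells without the Vα14Jα18 receptor. DN1eP-NKT cells (4) came from DN1eP after 10 days on OP9 cells with IL-2 and IL-7. Thymic NKT cells of stage 1 (5), stage 2 (7) and stage 3 (6) were sorted on CD44 and NK1.1. Per the labels, 2 library kits were used, without saying which library had which.

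The deposited values are FPKM, which the authors made from reads aligned to mm9 (TopHat2 2.0.6 and Cufflinks 2.1.1 by the submitters' processing notes). Values were checked to be at or above 0 and to differ between libraries. Rows of the same symbol were summed, and 86 symbols missing from a file and 13 with a failed estimate were left out, leaving 23168. Depth was read from the smallest step between FPKM values, which gave roughly 1.03 to 28.0 M fragments per library. The half-width of the deposited interval for a gene of 20 to 100 FPKM was 5.34% to 23.7%.

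Genes at 1 FPKM or more in at least 4 libraries were tested (11663), on log2(FPKM + 1) with no further scaling. All 26 libraries entered 1 limma fit (limma 3.58.1, R 4.3.3, trend and robust eBayes) with 1 coefficient per group. The 7 comparisons were DN1eP-NKT minus DN1eP, the mean of the 3 thymic stages minus DN1eP, stage 2 minus stage 1, stage 3 minus stage 2, and DN1eP-NKT minus each stage. P-values were adjusted by Benjamini and Hochberg over all genes at 0.05. The 26 gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, adjusted over all lists and comparisons, and again with an estimated correlation and with fry. Gene intervals in the tables are mm9, 1-based.

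The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names the sort gate genes and 5 regulators in every comparison, up to 4 called members of each list with the largest changes, and the 5 largest rises and falls among genes at a mean of 10 FPKM or more whose libraries do not overlap between the sides. Of the list members so named, the text prints a part, picked after their values were seen. A few genes, 1 of the regulators among them, are not reported here and were left out of the checks on single genes.

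The 2 sets of libraries were found after the data were seen, by the median FPKM of genes at 1 FPKM or more in each library, with a limit of 11 between them. Library set as a term, fits within each set, leaving out NKT-2 library 6 and NKT-3 library 5 together, stage means of the higher-median libraries, and controls split with library set as a term were therefore added later. The fits were tested on simulated data with 200 changed genes. Without a simulated difference between sets, each comparison recovered 52% to 77% of 2-fold and 94% to 99% of 4-fold changes. With the measured difference and no term for it, 19% to 56% of 2-fold changes were recovered, and DN1eP-NKT minus DN1eP called 5121 unchanged genes and the others at most 8. With the term, each of the 7 comparisons called between 3 and 12 and recovered 37% to 79% of 2-fold changes.

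The shared effect was compared with 20 simulations of unchanged groups per setting, those with split controls being added after the result was seen. Correlations with the stage means used all tested genes. Further settings tried were a pseudocount of 0.1, no filter, a filter of 5 FPKM, upper-quartile scaling, quantile normalization, array weights, only the compared groups in the fit, a replicate block, limma treat against a 2-fold change, the highest row per symbol, and leaving out each library in turn. Raw reads were not used here.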

Results

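The 26 libraries cover DN1eP precursors, NKT cells grown from them for 10 days (DN1eP-NKT) and thymic NKT cells of stages 1 to 3. On the first principal component, which carries 50.9% of the variance over 11663 tested genes, they lie in 2 sets of 13 libraries that do not follow the cell stage. The set with the higher median FPKM of expressed genes (12.97 to 13.92) holds all 4 DN1eP-NKT libraries and 9 thymic libraries. The set with the lower median (7.59 to 9.81) holds all 4 DN1eP libraries and 9 thymic libraries. Within the 18 thymic libraries, 8710 genes differ between the 2 sets with stage in the fit, 6294 of them higher in the higher-median set. DN1eP and DN1eP-NKT never share a set, so the total of changed genes in each comparison is given as tested and again with library set as a term. Since each of these groups lies in 1 set, the term is estimated from the 18 thymic libraries alone. That it holds for DN1eP and DN1eP-NKT is assumed and cannot be checked here. List counts after the first comparison are as tested, with those under the term added where they differ by over 1.5 times and by more than 1 gene. The labels do not say whether replicates come from separate animals, so every p-value measures only the spread between these samples. In DN1eP, libraries 2 to 4 correlated with each other at 0.934 to 0.94 and with library 1 at 0.883 to 0.907, and in DN1eP-NKT at 0.939 to 0.956 and 0.904 to 0.925. Whether libraries 2 to 4 share a pool of cells is not given in the sources used here, and if they do, n = 4 overstates the independent samples. Library 1 was also deeper, at 20.7 and 16.6 M fragments against 1.03 to 2.59 M in libraries 2 to 4. Its deposited rows carried another set of gene intervals than theirs. A difference in sequencing or processing can thus not be told apart from a difference in cells.

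**Figure D1:**
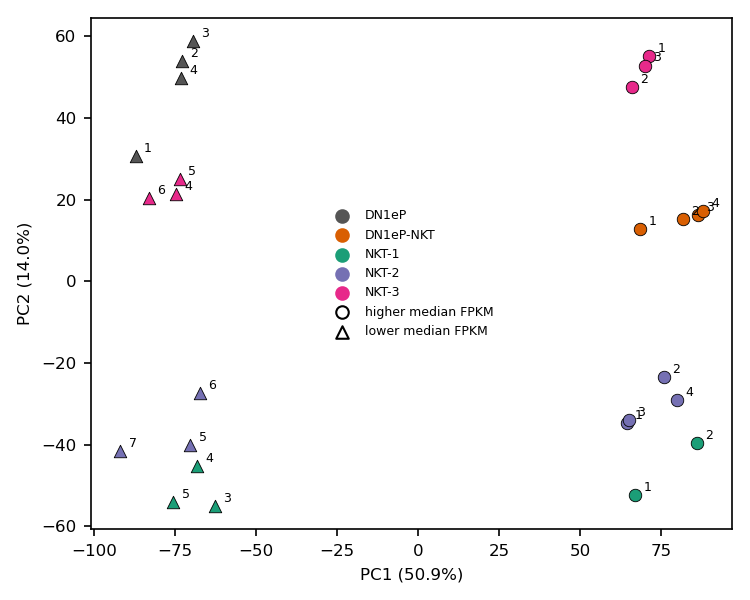
First 2 principal components of log2(FPKM + 1) over 11663 genes. Colours give the group, shapes the set of libraries by median FPKM, and numbers the replicate.

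DN1eP-NKT cells differed from their DN1eP precursors in proliferation genes and in the receptor for the IL-2 used in the culture. Il2ra, the alpha chain of that receptor, rose from 9.89 ± 3.30 to 107 ± 9.69 FPKM (mean ± SD, n = 4 and 4). It encodes CD25, and DN1eP were sorted as CD25-negative. Low Il2ra in DN1eP thus goes with the gate and is not independent evidence of a change. The proliferation marker Mki67 rose from 1.55 ± 0.43 to 106 ± 4.95 FPKM, and granzyme B (Gzmb) from 437 ± 362 (256 without DN1eP library 1, which holds 978) to 4690 ± 597. The chemokine gene Ccl5 fell from 8050 ± 1910 to 171 ± 36.3 FPKM, Xcl1 from 1050 ± 139 to 87.8 ± 69.1 (53.3 without DN1eP-NKT library 1), and the inhibitory receptor gene Pdcd1 from 298 ± 142 to 5.61 ± 0.67. Il17f, at 126 ± 86.0 FPKM in DN1eP, and Prss34, a mast cell protease gene at 277 ± 161, are listed at 0 in DN1eP-NKT. In all, 6136 genes changed, 4226 higher and 1910 lower in DN1eP-NKT, with a median log2 fold change of 0.50 over all genes. The fit with library set as a term gave 3748 (1766 higher and 1982 lower) and a median of -0.05, with 2376 genes called in the same direction by both fits.

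Of 30 cell cycle genes, 28 rose in DN1eP-NKT and 0 fell (28 adjusted over the list alone, camera adjusted p = 1.68e-14). These included Cdc20 (log2 fold change 5.26 ± 0.62 SE), Plk1 (5.03 ± 0.55) and Aurkb (4.68 ± 0.43). In the fit with library set as a term 26 rose. Of 23 IL-2 and STAT5 response genes, 16 rose and 3 fell (16 and 4 adjusted over the list alone, camera adjusted p = 0.00217, adjusted p = 0.0726 with an estimated correlation). Socs1 and Ccnd3 rose by 5.61 ± 1.08 and 4.32 ± 0.85, and by 2.13 ± 0.31 and 1.80 ± 0.45 with library set as a term. Cholesterol synthesis genes rose in 13 of 18 cases with 0 lower (13 adjusted over the list alone, camera adjusted p = 0.000275). Sqle rose by 3.93 ± 0.35. Of 16 glycolysis genes, 9 rose and 0 fell (9 adjusted over the list alone, camera adjusted p = 0.00878, adjusted p = 0.366 with an estimated correlation), including the lactate carrier gene Slc16a3 (4.47 ± 0.82). Markers of fibroblasts and stroma, the kind of cell in the OP9 layer, rose in 15 of 18 cases (16 adjusted over the list alone, camera adjusted p = 5.97e-09, adjusted p = 0.0991 with an estimated correlation). Cxcl12 was at 137 ± 62.9 FPKM, Fn1 at 44.3 ± 26.2 and Col1a1 at 30.2 ± 20.3 in DN1eP-NKT. Lif rose by 5.78 ± 0.44, Lgals3 by 4.67 ± 0.37, Il13 by 5.27 ± 0.93 and the Notch target Dtx1 by 4.52 ± 0.80. Part of some of these rises may go with library set. In stage 1, Dtx1 was at 7.8 and 10.3 FPKM in higher-median and 0.323 to 1.39 in lower-median libraries. Il13 was at 55.3 and 104 against 4.38 to 12.4. Slc16a3 was at 7.68 and 9.6 against 0.0433 to 0.391, and Cdc20 at 49.5 and 59.7 against 8.45 to 12.7. Without DN1eP-NKT library 1, the log2 fold change was 5.07 for Slc16a3, 5.68 for Fn1 and 5.29 for Col1a1, against 4.47, 4.96 and 4.41 with it. That library held Col1a1 at 2.43 FPKM against 28.6 to 49 in libraries 2 to 4. Sqle (24.3 against 45.7 to 50.9) and Lif (32.7 against 61.8 to 81.3) were also low there, but Lgals3 (683 against 528 to 588) was not. Whether RNA of OP9 cells is in the DN1eP-NKT libraries was not tested. Rises in DN1eP-NKT, here and against the thymic stages, can thus not be credited to NKT cells alone. The fit with library set as a term had 14 IL-2 and STAT5 response genes higher and 1 lower, and 12 cholesterol synthesis, 9 glycolysis and 13 stroma genes higher, with each list called (camera adjusted p = 1.17e-05, 2.53e-09, 0.000852 and 5.54e-11). At an estimated correlation the glycolysis and stroma calls under the term were lost (adjusted p = 0.284 and 0.0879).

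The fall in DN1eP-NKT was spread over T cell and IL-17 genes. Of 19 NKT17 genes, 14 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 6.67e-08, adjusted p = 0.107 with an estimated correlation). The fit with library set as a term had 9 lower and 1 higher (camera adjusted p = 0.000583, adjusted p = 0.356 with an estimated correlation), with a median log2 fold change of -1.54 against -2.81. Blk was at -4.79 ± 0.67 and Il23r at -4.02 ± 0.61. Of 21 TCR complex and signalling genes, 12 fell and 4 rose (12 and 5 adjusted over the list alone, camera adjusted p = 4.98e-05). Cd3e was at -2.17 ± 0.47 and Cd3g at -2.1 ± 0.35. Within stage 1, Cd3e was at 277 and 356 FPKM in the higher-median libraries and at 877 to 1130 in the lower-median libraries. Cd3g was at 651 and 921 FPKM against 1350 to 2090, so part of these falls may go with library set. Gamma-delta T cell markers fell in 6 of 7 cases (6 adjusted over the list alone, camera adjusted p = 0.000479). NKT2 genes fell in 7 of 16 with 2 higher (7 and 2 adjusted over the list alone, camera adjusted p = 0.000463, adjusted p = 0.146 with an estimated correlation). Folr4 was at -5.47 ± 0.46, Ccr9 at -4.88 ± 0.79 and Ramp3 at -6.34 ± 0.83, the last 2 at -6.21 and -7.61 without DN1eP library 1. With library set as a term 14 TCR complex and signalling, 5 gamma-delta and 8 NKT2 genes were lower and 0, 0 and 1 higher, with each list called (camera adjusted p = 0.000443, 0.00103 and 0.000579). At an estimated correlation the TCR and NKT2 calls under the term were lost (adjusted p = 0.236 and 0.236). NKT1 and cytotoxic genes went both ways, 14 lower and 8 higher of 31 (15 and 8 adjusted over the list alone, camera adjusted p = 0.000815, adjusted p = 0.161 with an estimated correlation). In the fit with library set as a term 8 were lower and 3 higher, and the list was no longer called (camera adjusted p = 0.2). Ncr1 was at -2.94 ± 0.51 (-3.78 without DN1eP-NKT library 1) and Tyrobp at -4.51 ± 0.83. Myeloid and dendritic genes fell in 6 of 15 cases and rose in 2 (7 and 2 adjusted over the list alone, camera adjusted p = 0.000626, adjusted p = 0.0868 with an estimated correlation), and Mpo fell from 86.0 ± 123 FPKM in DN1eP, where library 1 holds 271 and the mean without it is 24.4. That list was no longer called either with library set as a term, where 6 of its genes were lower and 1 higher (camera adjusted p = 0.144, median log2 fold change -0.14 against -1.39).

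Of the genes of the sort gate, Cd24a (-2.39 ± 0.55), Cd27 (-2.09 ± 0.24), Slamf6 (-2.60 ± 0.58), Cxcr3 (-1.50 ± 0.42) and Klrb1c (-3.70 ± 0.40) fell in DN1eP-NKT, while Cd44 (-0.07 ± 0.35) and Cd5 (-0.11 ± 0.39) gave adjusted p = 0.882 and 0.819. Among the regulators Tbx21 rose by 2.31 ± 0.93 (adjusted p = 0.0396). Zbtb16 (0.58 ± 0.88), Gata3 (-0.16 ± 0.20) and Egr2 (-0.16 ± 0.39) did not pass the test. With library set as a term Tbx21 stood at -0.59 ± 0.35 (adjusted p = 0.204) and Zbtb16 at -2.15 ± 0.33 (adjusted p = 1.78e-05). The largest rises among genes of at least 10 FPKM whose libraries did not overlap included Ube2s (6.26 ± 1.53), Tgfb1 (6.24 ± 1.85), Lmnb1 (6.07 ± 1.28) and Raly (5.99 ± 1.72), and the largest falls included Rn4.5s (-6.80 ± 2.48) and Rpl34 (-6.02 ± 2.49). Tgfb1 (0.15 ± 0.25), Raly (0.47 ± 0.43), Rn4.5s (-0.20 ± 1.89) and Rpl34 (-0.05 ± 2.21) were no longer called with library set as a term. In the higher-median set, Rpl34 was at 1470, 2150 and 2220 FPKM in library 1 of DN1eP-NKT, NKT-1 and NKT-2. The other libraries of that set held 0.00335 to 27.7, so Rpl34 went with depth inside the set. Ube2s and Lmnb1 also differed between sets within stage 1. Ube2s was at 228 and 358 FPKM in its higher-median libraries and at 4.76 to 19.7 in its lower-median libraries. Lmnb1 was at 118 and 87 FPKM against 2.22 to 4.88, so part of these rises may go with library set. The share of higher calls was 68.9% as deposited, 55.6% with upper-quartile scaling and 48.1% with quantile normalization, which moved the median of all genes by -0.37 and -0.58. Leaving out DN1eP library 1 put Cd24a at -3.06 and Slamf6 at -3.43, and leaving out DN1eP-NKT library 1 or 2 put Rn4.5s at -8.16 or -7.56, and library 1 Rpl34 at -7.81. With 1 library left out, the call was lost for Tbx21 without DN1eP libraries 1, 2, 3 or 4 or DN1eP-NKT libraries 2, 3 or 4 (2.13 to 2.37, adjusted p = 0.0589 to 0.0874), Rn4.5s without DN1eP-NKT libraries 3 or 4 (-5.74, adjusted p = 0.0788 to 0.0797), Rpl34 without DN1eP libraries 1, 2, 3 or 4 or DN1eP-NKT libraries 2, 3 or 4 (-6.18 to -5.08, adjusted p = 0.0669 to 0.12).

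**Figure D2:**
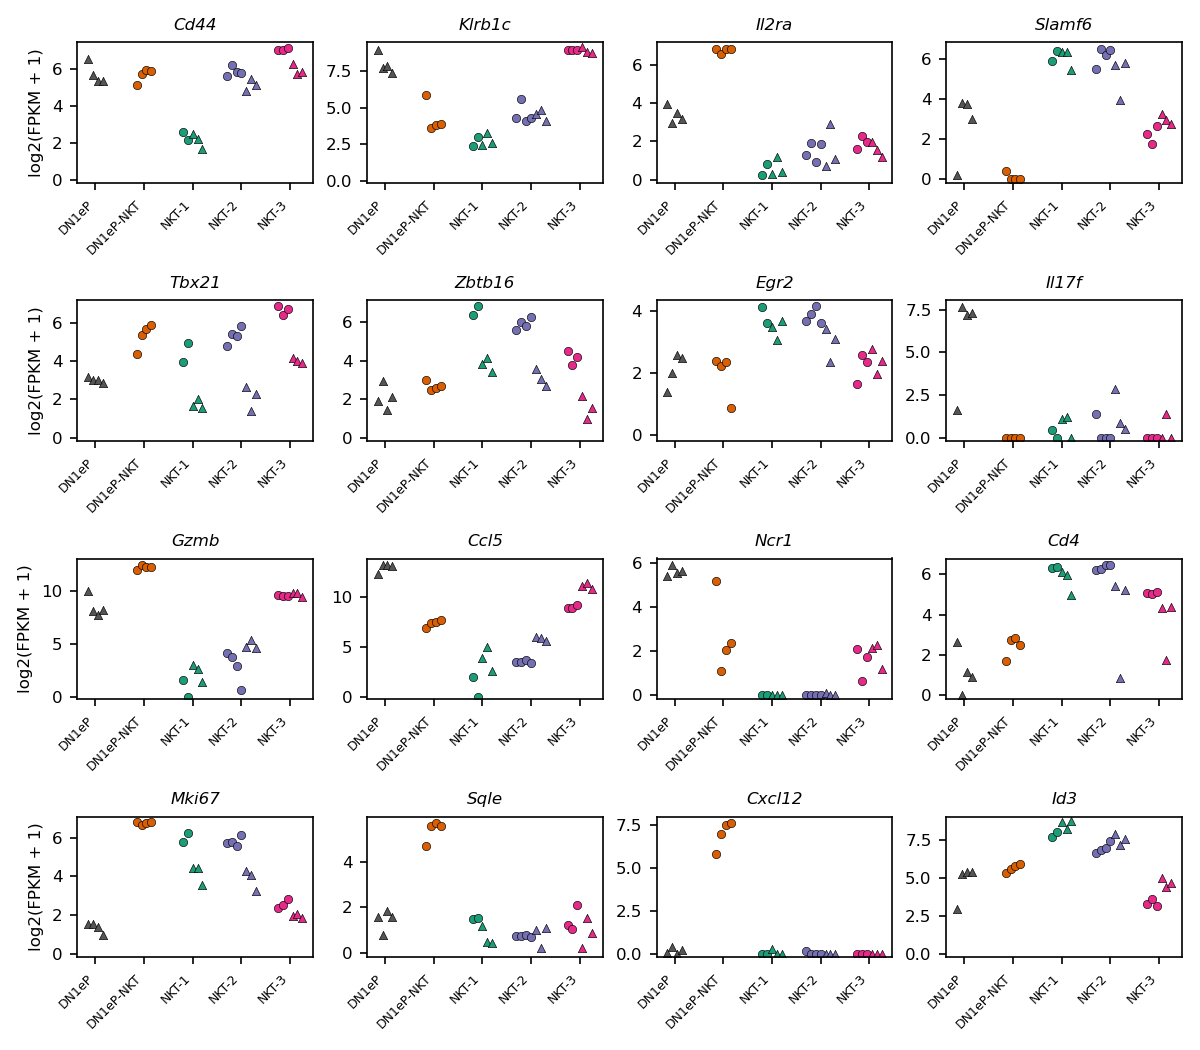
log2(FPKM + 1) of 16 genes in each library, with the group on the horizontal axis. Circles are libraries of the higher-median set and triangles those of the lower-median set.

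Averaged over stages 1 to 3, thymic NKT cells carried lower NK receptor and chemokine transcripts than DN1eP. Ccl5 stood at 8050 ± 1910 FPKM in DN1eP (n = 4) against 17 ± 13.4 (9.63 without NKT-1 library 4), 58.0 ± 8.57 and 2210 ± 420 in the lower-median libraries of stages 1, 2 and 3 (n = 3 each). Ncr1, which encodes the NK receptor NKp46, was at 49.3 ± 7.72 in DN1eP and at 2.83 ± 1.37 in the same stage 3 libraries. Ccl5 and Ncr1 are 2 of only 5 among 31 NKT1 and cytotoxic genes that passed the test as higher in DN1eP than in the lower-median stage 3 libraries, a comparison added after the library sets were found. Cd4 went the other way, from 1.86 ± 2.34 in DN1eP (0.718 without library 1) to 53.0 ± 20.1, 26.4 ± 22.2 and 13.7 ± 9.74. In all 3264 genes changed, 1651 higher and 1613 lower in NKT cells. A fit with library set as a term gave 4112 (1691 higher and 2421 lower), 2635 of the calls being shared, and the lower-median libraries alone gave 3322 (1295 and 2027).

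Of 31 NKT1 and cytotoxic genes, 27 fell in the NKT mean and 0 rose (28 adjusted over the list alone, camera adjusted p = 5.24e-26). These included Ccl5 (-7.16 ± 0.64), Tyrobp (-5.36 ± 0.65), Ccl4 (-5.32 ± 0.53), Prf1 (-3.19 ± 0.25) and Gzmb (-3.45 ± 0.54). For Gzmb and Prf1 the fall came from stages 1 and 2 and was not seen in stage 3. Gzmb was at 210 to 978 FPKM in DN1eP, and at 0 to 6.96, 0.663 to 40.2 and 680 to 889 in stages 1, 2 and 3. Prf1 was at 36.3 to 88.5 FPKM in DN1eP, and at 0 to 1.88, 0.434 to 1.82 and 38.1 to 59 in the same order. NKT17 genes fell in 12 of 19 cases and rose in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 2.03e-05, adjusted p = 0.198 with an estimated correlation). Il17f was at -5.42 ± 0.67, Il1r1 at -2.84 ± 0.42 and Il23r at -2.76 ± 0.48. IL-2 and STAT5 response genes fell in 12 of 23 and rose in 2 (12 and 3 adjusted over the list alone, camera adjusted p = 3.09e-05). Cell cycle genes rose in 26 of 30 with 0 lower (26 adjusted over the list alone, camera adjusted p = 2.26e-15). Mki67 rose by 2.70 ± 0.42 and Plk1 by 2.95 ± 0.43. Replication-dependent histone genes, whose near-identical copies make single values uncertain, rose in 6 of 11 (7 adjusted over the list alone, camera adjusted p = 0.00483, adjusted p = 0.118 with an estimated correlation). Hist1h2ab was at 2.12 ± 0.31. Trafficking and residency genes fell in 8 of 18 and rose in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00116, adjusted p = 0.0824 with an estimated correlation). Cd69 was at -3.09 ± 0.58. Il17rb rose by 3.17 ± 0.46, Il13 by 2.56 ± 0.73, Id3 by 1.77 ± 0.35 and Lmo4 by 2.18 ± 0.36. The glycolysis genes Hk1 (2.53 ± 0.51) and Pgam1 (2.38 ± 0.45) rose, and the sterol regulator gene Insig1 (-2.23 ± 0.28) fell. Hk1 was at 0.704 to 5.06 FPKM in DN1eP, 5.98 to 14.1 in lower-median and 38.3 to 46.6 in higher-median thymic libraries. Pgam1 was at 10.1 to 33.8, 21.2 to 82.9 and 74.6 to 241 FPKM in the same order. Of 16 glycolysis genes, 7 had an unadjusted limma p under 0.05, in either direction. Kit (-1.95 ± 0.20), Cpa3 (-4.44 ± 0.47), Ctsg (-3.15 ± 0.26), Mpo (-5.39 ± 0.38), Cd79b (-3.54 ± 0.63), Txk (-1.78 ± 0.19), Ptpn22 (-1.55 ± 0.16) and the gamma-delta T cell genes Blk (-2.02 ± 0.52) and 5830411N06Rik (-2.85 ± 0.45) also fell. Without DN1eP library 1, Il17f was at -6.85, Ccl4 at -5.97, 5830411N06Rik at -3.70, Mpo at -4.53 and Id3 at 1.18.

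In the sort gate, Cd5 (2.02 ± 0.31) and Slamf6 (2.1 ± 0.45) rose in the NKT mean, and Cd44 (-0.97 ± 0.28), Il2ra (-2.11 ± 0.29), Cd24a (-2.45 ± 0.43), Cd27 (-0.81 ± 0.19), Cxcr3 (-1.07 ± 0.33) and Klrb1c (-2.60 ± 0.31) fell. The fall of Klrb1c came from stages 1 and 2. It was at 170 to 495 FPKM in DN1eP, and at 4.2 to 8.47, 15.8 to 48.6 and 440 to 563 in stages 1, 2 and 3. Stage 3 also overlapped DN1eP for Cd44 (52 to 145 against 39.7 to 94.7 FPKM) and Cxcr3 (141 to 345 against 123 to 423). In the NKT mean, Zbtb16 (2.06 ± 0.69) and Egr2 (0.99 ± 0.30) rose, while Tbx21 (1.03 ± 0.73) and Gata3 (0.20 ± 0.15) did not pass. Zbtb16 depended on library set. It was at 1.75 to 6.77 FPKM in DN1eP, which lies in the lower-median set. In the lower-median libraries of stages 1, 2 and 3 it was at 9.77 to 16.6, 5.51 to 11 and 0.956 to 3.52 FPKM. The largest rises among genes of at least 10 FPKM whose libraries did not overlap were Ptms (3.33 ± 1.07), Ddit4 (3.15 ± 1.15), Lbh (3.12 ± 0.84), Mta1 (3.06 ± 0.71) and Ldb1 (3.02 ± 0.83), which stood at 1.17 ± 0.26, 0.83 ± 0.24, 1.42 ± 0.17, 1.66 ± 0.24 and 1.34 ± 0.19 with library set as a term. Car2 fell by 5.18 ± 0.43. DN1eP library 1 differed from libraries 2 to 4 in many of these genes, with Il17f at 2.16 FPKM against 146 to 200. Leaving that library out put Slamf6 at 1.28 and Cd24a at -3.12. Upper-quartile scaling moved the median of all genes in this comparison by -0.13 log2 and quantile normalization by -0.20. Without DN1eP library 2, 2060 genes changed, and without library 3, 2033. Without NKT-2 library 6 and NKT-3 library 5, which hold B cell and erythroid transcripts, the count was 3803. With 1 library left out, the call was lost for Cd44 without DN1eP library 1 (-0.69, adjusted p = 0.0874), Cxcr3 without DN1eP library 1 (-0.69, adjusted p = 0.138), Zbtb16 without DN1eP libraries 1, 3 or 4 (1.84 to 2.06, adjusted p = 0.0687 to 0.105). It was also lost for Egr2 without DN1eP libraries 1 or 2 (0.75 to 0.95, adjusted p = 0.0604 to 0.0971), Ptms without DN1eP libraries 1, 2, 3 or 4 (3.31 to 3.36, adjusted p = 0.0502 to 0.0651), Ddit4 without DN1eP libraries 1, 2, 3 or 4 or NKT-1 libraries 1 or 2 or NKT-2 libraries 1, 2, 3 or 4 or NKT-3 libraries 1, 2 or 3 (2.88 to 3.22, adjusted p = 0.0522 to 0.102).

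Between stages 1 and 2 of thymic NKT cells the fit without further terms called few genes, among them the hyaluronan receptor gene Cd44, on which the stages were sorted. Cd44 rose from 3.81 ± 1.10 to 49.0 ± 16.1 FPKM (n = 5 and 7). In all 27 genes changed, 15 higher and 12 lower in stage 2, a count that hangs on the fit, with 7407 under array weights and 1 with only the compared groups. Array weights were 0.202 and 0.242 in the higher-median stage 1 libraries and 1.2 to 2.94 in the lower-median ones. In stage 2 they were 1.57 to 3.34 in the higher-median and 0.191 to 0.248 in the lower-median libraries. That setting thus mostly compared lower-median stage 1 with higher-median stage 2 libraries, so the 7407 take in the difference between sets. All 27 were also called with library set as a term, which called 93 (59 higher and 34 lower). Klrb1c (1.82 ± 0.33), Xcl1 (2.42 ± 0.49) and Fgl2 (2.44 ± 0.51) rose, as did the IL-17 program genes Il23r (3.03 ± 0.50), Il1r1 (2.67 ± 0.45) and Il17re (1.90 ± 0.35) and the phosphatase gene Ptpn22 (0.89 ± 0.17). Lef1 (-1.23 ± 0.25), Rln3 (-2.81 ± 0.53), Akr1c18 (-2.52 ± 0.48), Slc15a1 (-1.61 ± 0.33) and Lztfl1 (-1.46 ± 0.28) fell. Of 19 NKT17 genes 3 rose (10 adjusted over the list alone, camera adjusted p = 1.51e-24). Of 31 NKT1 and cytotoxic genes 2 rose (10 adjusted over the list alone, camera adjusted p = 2.49e-15), and in neither list did a gene fall. Under the term for library set 7 NKT17 and 8 NKT1 and cytotoxic genes rose. NKT2 genes moved down as a list with 1 called (1 adjusted over the list alone, camera adjusted p = 0.00441, adjusted p = 0.241 with an estimated correlation). Immediate early and stress genes moved up as a list of 18 with 0 called by limma and 3 at an unadjusted p under 0.05 (0 adjusted over the list alone, camera adjusted p = 9.39e-06, adjusted p = 0.224 with an estimated correlation). Il2ra (0.93 ± 0.31), Cd24a (0.34 ± 0.45), Cd5 (-0.29 ± 0.32), Cd27 (-0.44 ± 0.20), Slamf6 (-0.35 ± 0.48), Cxcr3 (0.75 ± 0.35), Zbtb16 (-0.20 ± 0.73), Tbx21 (1.14 ± 0.77), Gata3 (-0.37 ± 0.16) and Egr2 (-0.13 ± 0.32) were not called. With array weights Zbtb16 was called in the other direction (1.62, adjusted p = 0.000886, against 0.244 to 1 in the other settings). Under those weights the difference between library sets enters this value. NKT-2 library 6 holds Il1r1 at 59.6 FPKM and the B cell gene Cd79a at 42.3. Without NKT-1 library 3, 7 genes changed, and without NKT-1 library 5, 17, while without NKT-2 library 6 and NKT-3 library 5 it was 24. With 1 library left out, the call was lost for Klrb1c without NKT-1 library 3 (1.75, adjusted p = 0.0518), Xcl1 without NKT-1 libraries 1, 3 or 5 or NKT-2 libraries 2 or 5 (1.90 to 2.38, adjusted p = 0.062 to 0.104), Lef1 without NKT-1 libraries 1, 2 or 5 or NKT-2 library 5 (-1.23 to -1.15, adjusted p = 0.0508 to 0.104). It was also lost for Il17re without NKT-1 library 3 (1.83, adjusted p = 0.0555), Ptpn22 without NKT-1 libraries 1, 3 or 5 (0.84 to 0.86, adjusted p = 0.0529 to 0.0667), Fgl2 without NKT-1 libraries 1, 2, 3, 4 or 5 or NKT-2 libraries 1, 2, 3 or 4 (2.17 to 2.56, adjusted p = 0.0505 to 0.113). It was also lost for Rln3 without NKT-1 libraries 2 or 5 (-2.70 to -2.41, adjusted p = 0.0521 to 0.0641), Akr1c18 without NKT-1 libraries 3 or 4 (-2.34 to -2.28, adjusted p = 0.0536 to 0.0733), Slc15a1 without NKT-1 libraries 1, 2, 3 or 4 or NKT-2 libraries 1, 4, 6 or 7 (-1.65 to -1.50, adjusted p = 0.0505 to 0.0944). It was also lost for Lztfl1 without NKT-1 libraries 2, 3, 4 or 5 (-1.45 to -1.41, adjusted p = 0.0521 to 0.0667).

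Stage 3 cells gained NK receptors and cytotoxic genes and lost proliferation genes compared with stage 2. Klrb1c, the NK1.1 gene used for the sort, rose from 24.1 ± 11.6 to 492 ± 43.4 FPKM (n = 7 and 6), Gzmb from 18.1 ± 13.1 to 777 ± 85.8, and perforin (Prf1) from 1.12 ± 0.49 to 46.3 ± 9.86. The survival gene Bcl2 rose from 3.51 ± 2.81 to 52.7 ± 25.6, and Top2a fell from 152 ± 51.1 to 12.3 ± 3.51. In all 1460 genes changed, 456 higher and 1004 lower in stage 3, and all 1460 were also called with library set as a term, which called 3438 (1266 higher and 2172 lower). The higher-median libraries alone gave 3269 genes (1352 and 1917) and the lower-median libraries 830 (276 and 554), with 741 in both. The share of higher calls was 31.2% as deposited, 43.7% with upper-quartile scaling and 45.6% with quantile normalization, which moved the median of all genes by 0.11 each.

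Of 31 NKT1 and cytotoxic genes, 27 rose in stage 3 and 0 fell (29 adjusted over the list alone, camera adjusted p = 7.98e-52). Gzma was at 5.75 ± 0.53, Ifng at 3.84 ± 0.63, Klrc1 at 6.34 ± 0.50 and Klrc2 at 5.89 ± 0.51. The Klr genes Klre1 (6.83 ± 0.39), Klra5 (6.65 ± 0.48) and Klra9 (5.93 ± 0.42) also rose, though families of near-identical members make each of these values uncertain. Cell cycle genes fell in 29 of 30 cases (30 adjusted over the list alone, camera adjusted p = 1.59e-41). Ccnb1 was at -3.67 ± 0.47. NKT2 genes fell in 12 of 16 with 0 higher (14 adjusted over the list alone, camera adjusted p = 2.37e-13). Ccr7 was at -4.89 ± 0.51, Ccr9 at -4.16 ± 0.62, Il17rb at -3.77 ± 0.46 and Ccr4 at -3.74 ± 0.53. NKT17 genes fell in 12 of 19 (15 adjusted over the list alone, camera adjusted p = 1.00e-09, adjusted p = 0.0706 with an estimated correlation). Il23r was at -2.59 ± 0.48, Il1r1 at -2.53 ± 0.42 and Blk at -2.80 ± 0.52. NKT specification genes fell in 6 of 23 with 0 higher (7 adjusted over the list alone, camera adjusted p = 0.00646, adjusted p = 0.161 with an estimated correlation). These included Id3 (-3.17 ± 0.36), Myb (-2.85 ± 0.47) and Vdr (-2.68 ± 0.36). IL-2 and STAT5 response genes rose in 8 of 23 with 0 lower (9 and 1 adjusted over the list alone, camera adjusted p = 3.01e-09). Immediate early and stress genes rose in 3 of 18 (4 adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.304 with an estimated correlation). Rgs1 rose by 3.22 ± 0.54 and Btg2 by 1.43 ± 0.23. Glycolysis genes fell in 5 of 16 (6 adjusted over the list alone, camera adjusted p = 0.00181, adjusted p = 0.266 with an estimated correlation). Pgk1 was at -1.28 ± 0.23 and Ldha at -1.10 ± 0.21. Under the term for library set 11 NKT specification genes fell and 2 rose, 6 immediate early and stress genes rose, and 8 glycolysis genes fell.

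Itga1 (3.77 ± 0.35), Ubash3a (2.49 ± 0.25), Cd2 (1.49 ± 0.36), Fcgr3 (2.53 ± 0.28) and Tyrobp (3.55 ± 0.65) rose in stage 3. Igfbp4 (-5.25 ± 0.90), Pcsk1 (-4.43 ± 0.30), Emb (-4.30 ± 0.29), Themis (-2.84 ± 0.35), Lmo4 (-2.82 ± 0.37) and Tcf7 (-1.97 ± 0.35) fell. Of the sort gate and regulators, Cd44 (0.96 ± 0.28) and Cxcr3 (1.41 ± 0.33) rose, and Slamf6 (-3.13 ± 0.45) and Egr2 (-1.18 ± 0.30) fell. Il2ra (0.24 ± 0.29), Cd24a (-0.59 ± 0.43), Cd5 (-0.58 ± 0.31), Cd27 (-0.0021 ± 0.19) and Gata3 (-0.18 ± 0.15) were not called. Zbtb16 (-1.85 ± 0.69, adjusted p = 0.0856) and Tbx21 (1.38 ± 0.73, adjusted p = 0.283) were not called either, and stood at -1.66 ± 0.22 and 1.58 ± 0.23 with library set as a term (adjusted p = 9.69e-07 and 3.91e-06). Without NKT-2 library 6 and NKT-3 library 5, 1360 genes changed. With 1 library left out, the call was lost for Cd44 without NKT-2 library 5 or NKT-3 libraries 1, 2 or 3 (0.83 to 0.85, adjusted p = 0.0551 to 0.0687). The call was gained for Zbtb16 without NKT-2 libraries 6 or 7 or NKT-3 library 1 (-2.19 to -2.13, adjusted p = 0.0339 to 0.0467).

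Against stage 1 cells, DN1eP-NKT cells held far more granzyme transcript and little Slamf6. Gzmb was at 4690 ± 597 FPKM in DN1eP-NKT (n = 4) and at 1.02 ± 1.45 in the higher-median stage 1 libraries (n = 2, at 0 and 2.05). Gzma was at 4410 ± 1370 and 4.06 ± 2.35 (2.39 and 5.72), and Slamf6, which encodes the adhesion receptor Ly108, at 0.08 ± 0.17 (0 without DN1eP-NKT library 1) and 71.5 ± 18.5. In all 2326 genes changed, 1364 higher and 962 lower, and with library set as a term 2528, with 1696 shared and the majority turned to lower (1192 higher and 1336 lower). Of 31 NKT1 and cytotoxic genes, 27 rose and 0 fell (28 adjusted over the list alone, camera adjusted p = 3.43e-22). Klrc1 was at 6.06 ± 0.60, Hopx at 5.08 ± 0.97 and Ifng at 4.64 ± 0.76. IL-2 and STAT5 response genes rose in 21 of 23 with 0 lower (21 adjusted over the list alone, camera adjusted p = 7.15e-17). Cish rose by 4.70 ± 0.32. Cholesterol synthesis genes rose in 15 of 18 (16 and 1 adjusted over the list alone, camera adjusted p = 4.79e-10). Sqle rose by 4.35 ± 0.33. Stroma markers rose in 16 of 18 (16 adjusted over the list alone, camera adjusted p = 2.49e-15). Cxcl12 rose by 6.90 ± 0.24, Fn1 by 5.05 ± 0.38 and Col1a2 by 4.42 ± 0.33. NKT2 genes fell in 11 of 16 with 0 higher (13 and 1 adjusted over the list alone, camera adjusted p = 1.69e-14). Folr4 was at -7.17 ± 0.43, Plac8 at -6.29 ± 0.57 and Ccr9 at -6.14 ± 0.75. NKT specification genes fell in 10 of 23 and rose in 2 (11 and 3 adjusted over the list alone, camera adjusted p = 0.000104, adjusted p = 0.0553 with an estimated correlation), and under the term for library set in 16 and 1. Sh2d1a was at -2.75 ± 0.40, Tox at -2.72 ± 0.30 and Vdr at -2.71 ± 0.44. Leaving out DN1eP-NKT library 1 put Fn1 at 5.77, Col1a2 at 5.07 and Plac8 at -5.55, and leaving out NKT-1 library 4 put Klrc1 at 6.77.

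Ifitm1 (8.89 ± 0.45), Ifitm2 (9.17 ± 0.67) and Ifitm3 (8.27 ± 0.64), a family whose similar members make single values uncertain, rose against stage 1, and Akr1c18 (-5.82 ± 0.55) and Ramp1 (-5.73 ± 0.33) fell. Kit (2.41 ± 0.24), Dtx1 (4.26 ± 0.76), Nrarp (3.11 ± 0.74), Rasgrp1 (3.34 ± 0.65), Itga1 (3.25 ± 0.43), Lif (4.40 ± 0.41), Cd22 (4.34 ± 0.22) and Mki67 (1.86 ± 0.51) rose, while Cd4 (-3.49 ± 0.85), Cd6 (-2.56 ± 0.29) and Trat1 (-2.05 ± 0.32) fell. In the higher-median stage 1 libraries Mki67 was at 54 and 74.3 FPKM, Dtx1 at 7.8 and 10.3 and Nrarp at 3.95 and 3.74. In DN1eP-NKT they were at 99.6 to 110, 26.1 to 97.9 and 11.3 to 21.8 FPKM. Of 30 cell cycle genes, 9 had an unadjusted limma p under 0.05 against stage 1, in either direction. Cd44 (3.45 ± 0.34), Il2ra (6.16 ± 0.35), Klrb1c (1.58 ± 0.38) and Tbx21 (2.49 ± 0.88, adjusted p = 0.0471) rose. Cd5 (-2.52 ± 0.37), Cd27 (-1.57 ± 0.23), Slamf6 (-5.99 ± 0.55), Gata3 (-0.66 ± 0.18) and Egr2 (-1.63 ± 0.37) fell, and Cd24a (0.09 ± 0.52), Cxcr3 (0.55 ± 0.40) and Zbtb16 (-2.23 ± 0.83) were not called. Tbx21 with library set as a term was at 0.75 ± 0.30 (adjusted p = 0.0713) and Zbtb16 at -3.87 ± 0.29 (adjusted p = 2.34e-11). The share of higher calls was 58.6% as deposited and 46.3% with quantile normalization, which moved the median of all genes by -0.36, while upper-quartile scaling moved it by -0.20. Without NKT-1 library 2, 3641 genes changed. With 1 library left out, the call was lost for Tbx21 without DN1eP-NKT libraries 1, 2, 3 or 4 or NKT-1 libraries 3, 4 or 5 (2.17 to 2.80, adjusted p = 0.0518 to 0.127). The call was gained for Zbtb16 without NKT-1 library 5 (-2.60, adjusted p = 0.0458).

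Against stage 2 cells, DN1eP-NKT cells held more Il2ra and Bcl2 and less Ramp1. Il2ra, the IL-2 receptor alpha chain gene, was at 107 ± 9.69 FPKM in DN1eP-NKT (n = 4) and 1.91 ± 0.88 in the higher-median stage 2 libraries (n = 4). Bcl2 was at 93.0 ± 7.01 and 5.32 ± 2.35, and Ramp1 at 0.58 ± 0.33 and 119 ± 43.0. In all 1637 genes changed, 1144 higher and 493 lower, with library set as a term 2406 (1420 and 986), and 1547 shared. The higher-median libraries alone gave 2837 (1611 and 1226). Of 31 NKT1 and cytotoxic genes 24 rose and 0 fell (27 adjusted over the list alone, camera adjusted p = 5.86e-19). Gzma was at 9.31 ± 0.59, Gzmb at 8.42 ± 0.62 and Klri2 at 5.03 ± 0.28. IL-2 and STAT5 response genes rose in 19 of 23 (20 adjusted over the list alone, camera adjusted p = 4.76e-18). Socs2 rose by 4.32 ± 0.27. Cholesterol synthesis genes rose in 14 of 18 (16 adjusted over the list alone, camera adjusted p = 1.37e-13). Sqle rose by 4.62 ± 0.31. Stroma markers rose in 15 of 18 (16 adjusted over the list alone, camera adjusted p = 7.37e-19). Cxcl12 rose by 6.93 ± 0.23. NKT2 genes fell in 10 of 16 with 0 higher (12 and 1 adjusted over the list alone, camera adjusted p = 2.40e-16). Folr4 was at -6.99 ± 0.40, Plac8 at -5.52 ± 0.54 (-4.77 without DN1eP-NKT library 1) and Ccr9 at -4.67 ± 0.70. NKT17 genes fell in 9 of 19 and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 2.72e-10, adjusted p = 0.063 with an estimated correlation). Il23r was at -3.14 ± 0.54 and Blk at -3.87 ± 0.59. Ifitm1 (8.97 ± 0.42), Ifitm2 (9.27 ± 0.62), Ifitm3 (7.50 ± 0.60) and Mki67 (1.78 ± 0.48) rose, and Ramp1 (-6.00 ± 0.30), Cd6 (-2.39 ± 0.27), Sh2d1a (-2.48 ± 0.38) and Tox (-2.40 ± 0.28) fell. Mki67 was at 99.6 to 110 FPKM in DN1eP-NKT and at 46.4 to 68.7 in the higher-median stage 2 libraries. Of 30 cell cycle genes, 9 had an unadjusted limma p under 0.05 against stage 2, in either direction.

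Il2ra (5.24 ± 0.33) rose against stage 2, and Cd5 (-2.23 ± 0.35), Cd27 (-1.13 ± 0.21), Slamf6 (-5.64 ± 0.51) and Egr2 (-1.50 ± 0.34) fell. Cd44 (0.11 ± 0.31), Cd24a (-0.25 ± 0.48), Cxcr3 (-0.20 ± 0.37), Klrb1c (-0.25 ± 0.35), Zbtb16 (-2.03 ± 0.78, adjusted p = 0.0855), Tbx21 (1.35 ± 0.82) and Gata3 (-0.30 ± 0.17) were not called. Zbtb16 with library set as a term stood at -3.20 ± 0.26 (adjusted p = 1.14e-10). The share of higher calls was 69.9% as deposited and 49.9% with quantile normalization, with the median of all genes moved by -0.36, and by -0.22 with upper-quartile scaling. Without NKT-2 library 6 and NKT-3 library 5, 1476 genes changed. Zbtb16 was called without NKT-2 library 7 (-2.37, adjusted p = 0.044).

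Against stage 3 cells, DN1eP-NKT cells held less NK1.1 and Xcl1 transcript and more proliferation transcripts. Of 31 NKT1 and cytotoxic genes 17 were not called, 10 fell and 4 rose in DN1eP-NKT (13 and 4 adjusted over the list alone, camera adjusted p = 5.03e-05, adjusted p = 0.0935 with an estimated correlation). Klrb1c was at 23.8 ± 22.0 FPKM in DN1eP-NKT (n = 4, 12.8 without library 1) and 498 ± 4.96 in the higher-median stage 3 libraries (n = 3). Xcl1 was at 87.8 ± 69.1 (53.3 without library 1) and 1020 ± 232, and Mki67 at 106 ± 4.95 and 5.03 ± 1.03. In all 2077 genes changed, 1645 higher and 432 lower, with library set as a term 3054 (2057 and 997), and 1905 shared. The higher-median libraries alone gave 3463 (2134 and 1329). Cell cycle genes rose in 29 of 30 (30 adjusted over the list alone, camera adjusted p = 9.13e-29). Ccna2 rose by 4.35 ± 0.61 and Plk1 by 4.16 ± 0.51. Stroma markers rose in 17 of 18 (17 adjusted over the list alone, camera adjusted p = 4.38e-19). Igfbp4 rose by 5.32 ± 1.04, while Cxcl12 is listed at 0 in stage 3. Igfbp4 is not particular to stroma here. It was at 17.5 to 70 FPKM in DN1eP-NKT, and at 249 and 468 in stage 1 and 103 to 195 in stage 2 libraries of the higher-median set. Cholesterol synthesis genes rose in 14 of 18 (15 adjusted over the list alone, camera adjusted p = 1.41e-11). Sqle rose by 4.21 ± 0.32. Glycolysis genes rose in 11 of 16 (13 adjusted over the list alone, camera adjusted p = 4.38e-05, adjusted p = 0.146 with an estimated correlation). Slc16a3 rose by 3.39 ± 0.75 (3.995 without DN1eP-NKT library 1). IL-2 and STAT5 response genes rose in 12 of 23 and fell in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 7.08e-05). Tnfrsf9 rose by 3.60 ± 0.33. TCR complex and signalling genes fell in 7 of 21 and rose in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 9.39e-06). At an estimated correlation that call held as tested and was lost under the term for library set (adjusted p = 0.0193 and 0.214). Cd3g was at -1.71 ± 0.32 and Trat1 at -2.65 ± 0.31. Immediate early and stress genes fell in 4 of 18 and rose in 1 (5 and 1 adjusted over the list alone, camera adjusted p = 4.91e-05, adjusted p = 0.26 with an estimated correlation), and under the term for library set in 10 and 2. Fos was at -3.38 ± 0.89 (-4.14 without NKT-3 library 5) and Btg2 at -2.39 ± 0.26.

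Lif (5.81 ± 0.40), Ifitm1 (5.88 ± 0.43), Cdkn1a (5.47 ± 0.35), Il13 (4.86 ± 0.85), Gzma (3.56 ± 0.61), Lgals3 (3.52 ± 0.34), Eomes (3.38 ± 0.42), Dtx1 (3.35 ± 0.73) and S1pr1 (2.95 ± 0.33) rose against stage 3. Folr4 (-6.21 ± 0.42), Itm2a (-4.60 ± 0.43), Spry2 (-4.49 ± 0.60), Klra6 (-3.71 ± 0.53), Ramp1 (-3.64 ± 0.31), Xcl1 (-3.62 ± 0.54), Itga4 (-1.85 ± 0.60) and Il7r (-1.70 ± 0.29) fell. Eomes was at 54.9 FPKM in DN1eP-NKT library 1 against 4.65 to 6.27 in the other 3, and rose by 2.61 without it. Klra6 was at -3.10 without DN1eP-NKT library 3. Il2ra (5.00 ± 0.34) rose, and Cd5 (-1.64 ± 0.36), Cd27 (-1.13 ± 0.22), Slamf6 (-2.51 ± 0.53), Cxcr3 (-1.61 ± 0.39) and Klrb1c (-4.64 ± 0.36) fell. Cd44 (-0.85 ± 0.32), Cd24a (0.34 ± 0.50), Zbtb16 (-0.18 ± 0.80), Tbx21 (-0.02 ± 0.85), Gata3 (-0.11 ± 0.18) and Egr2 (-0.32 ± 0.35) were not called. Zbtb16 with library set as a term stood at -1.55 ± 0.27 and Tbx21 at -1.47 ± 0.28 (adjusted p = 5.75e-05 and 0.000193). The share of higher calls was 79.2% as deposited, 59.8% with upper-quartile scaling and 48.7% with quantile normalization, which moved the median of all genes by -0.34 and -0.48. Without NKT-2 library 6 and NKT-3 library 5, 1792 genes changed. On leaving out 1 library, the call was lost for Itga4 without DN1eP-NKT libraries 2, 3 or 4 or NKT-3 libraries 1, 2 or 3 (-1.89 to -1.64, adjusted p = 0.0589 to 0.0916). The call was gained for Cd44 without NKT-3 libraries 5 or 6 (-1.01 to -0.99, adjusted p = 0.0337 to 0.0449).

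**Figure D3:**
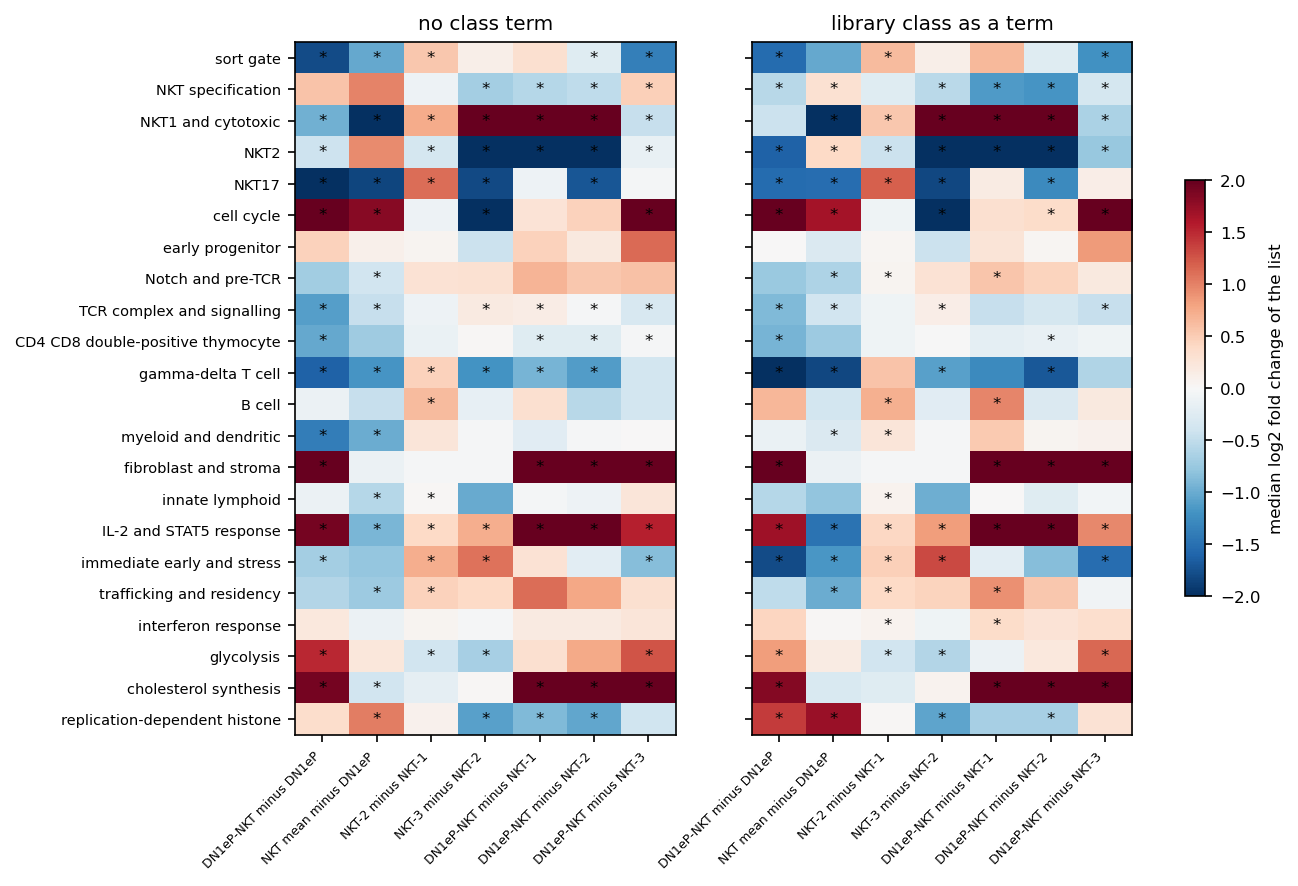
Median log2 fold change of the 22 gene lists long enough for camera in the 7 comparisons, as tested (left) and with library set, named class in the panels, as a term (right). Colours end at -2 and 2. Asterisks mark lists with a camera adjusted p under the threshold.

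The genes that changed from DN1eP to DN1eP-NKT were compared with those that changed from DN1eP to thymic NKT cells. Both rest on the same 4 DN1eP libraries, and genes are not independent replicates. The log2 fold changes correlated at r = 0.798, with 1349 genes higher in both against 598.2 by chance and 1105 lower in both against 264.2. Unchanged groups simulated with no difference between library sets gave r = 0.638 through the shared libraries alone, with a covariance of 0.171 against the measured 1.20. With the measured difference between sets simulated as well, they gave r = 0.945 and a covariance of 0.863. With library set as a term r was 0.70 against 0.709 simulated, the covariance 0.627 against 0.103, and 981 and 1345 genes were shared against 256 and 411.4 by chance. With the controls split 2 and 2, r was 0.674 against 0.791 in unchanged groups simulated with the same splits and the set difference. Splits with library set as a term gave 0.524 against 0.150 simulated, and a covariance of 0.514 against 0.0337. The split fits share no control library but still share the difference between sets, or its estimate.

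Each DN1eP-NKT library was correlated with the mean profile of each thymic stage. The Spearman correlation was 0.813 ± 0.005 with stage 1, 0.860 ± 0.004 with stage 2 and 0.852 ± 0.007 with stage 3 (mean ± SD, n = 4), across genes that are not independent replicates. Stage 2 was the nearest in 4 of 4 libraries, by 0.00821 over stage 3 and 0.0463 over stage 1, and the exact sign-flip p was 0.13 for both, the smallest that 4 libraries can give. With stage means from the higher-median libraries, to which DN1eP-NKT belongs, the values were 0.872, 0.891 and 0.875. By Pearson correlation stage 2 led stage 3 in 3 of 4 libraries (exact sign-flip p = 0.25), and over the 1000 most variable genes in 2 of 4 (exact sign-flip p = 0.5).

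The remaining lists are given for DN1eP-NKT against DN1eP. Immediate early and stress genes rose in 2 and fell in 5 of 18 (camera adjusted p = 0.0297, adjusted p = 0.575 with an estimated correlation). With library set as a term 0 rose and 9 fell (camera adjusted p = 0.00193, adjusted p = 0.414 with an estimated correlation). NKT specification genes rose in 6 and fell in 7 of 23 (camera adjusted p = 0.202), and under the term in 2 and 10 (camera adjusted p = 0.0195, adjusted p = 0.236 with an estimated correlation). Early progenitor genes had 6 of 20 members tested, of which 2 rose and 0 fell from DN1eP to DN1eP-NKT (camera adjusted p = 0.885). Notch and pre-TCR genes rose in 5 and fell in 5 of 12 (camera adjusted p = 0.555). Interferon response genes rose in 6 and fell in 5 of 20 (camera adjusted p = 0.828), and with library set as a term in 8 and 1 (camera adjusted p = 0.0597). Innate lymphoid genes rose in 2 and fell in 6 of 15 (camera adjusted p = 0.169). Trafficking and residency genes rose in 6 and fell in 6 of 18 (camera adjusted p = 0.152). Replication-dependent histone genes rose in 3 and fell in 0 of 11 (camera adjusted p = 0.795). With library set as a term 6 rose and 1 fell (camera adjusted p = 0.016, adjusted p = 0.229 with an estimated correlation). B cell genes rose in 1 and fell in 2 of 8 (camera adjusted p = 0.535). CD4 CD8 double-positive thymocyte genes fell in 7 and rose in 2 of 13 (10 and 2 adjusted over the list alone, camera adjusted p = 0.00157), and with library set as a term in 4 and 1 (camera adjusted p = 0.0315, adjusted p = 0.135 with an estimated correlation). The thymic epithelium (4 tested genes), erythroid (3) and sex-linked (2) lists were too short for camera, with 1, 1 and 1 higher and 2, 0 and 0 lower, and 0 mitochondrially encoded genes are in the files. The sort gate list, whose genes were used to pick the cells and so are not independent evidence of a direction, moved down in DN1eP-NKT (5 fell and 1 rose of 8, 5 and 1 adjusted over the list alone, camera adjusted p = 0.00551).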

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

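The tests of cell stage behind the library sets, B cell RNA, NKT17 cells, NK cells and gamma-delta T cells, and the counts with library set as a term, were chosen only after the result was seen.

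Of 710 groups tested for a library far from the others of its group, 115 stood out (16.2%). Chance gives about 1 in 20 for normally distributed values, a rate that was not tested here and does not apply to the 29 of them where every other library of the group is at 0. DN1eP library 1 stood apart most often, its values including (FPKM unless named) 5830411N06Rik 16.8, Ccl4 46.7, Ccl5 5220, Ccr4 0.814, Ccr7 4.76, Ccr9 1.93, Cd2 804, Cdkn1a 1.57, Col1a1 0.0433, Col1a2 0.138, Ddit4 0.197, Folr4 55.5, Gzma 954, Id3 6.7, Ifng 136, Il17f 2.16, Itga4 2.44, Klrc1 433, Klre1 283, Mpo 271, Myb 1.65, Pdcd1 85.2, Prss34 36.7, Ptms 0.102, Ramp3 7.04, S1pr1 18, Slc16a3 0.0893, Tcf7 73.8, Tyrobp 115, near 9210 genes at 1 FPKM or more, M fragments 20.7. In DN1eP-NKT library 1 the values were Akr1c18 0.0636, Dtx1 26.1, Eomes 54.9, Fn1 6.86, Hopx 48.6, Il17rb 6.81, Il7r 167, Itga1 4.21, Klra9 66, Klrb1c 56.8, Klri2 17.9, Mpo 0.0262, Raly 163, S1pr1 25.6, Slamf6 0.329, Sqle 24.3, Tgfb1 88.9, Xcl1 191, M fragments 16.6. In NKT-2 library 6 they were Car2 2.77, Cd24a 6.09, Cd4 0.843, Emb 110, Fn1 0.346, Folr4 57.2, Il1r1 59.6, Il7r 406, Lef1 17.4, Slamf6 14.8, Socs2 2.8, Sqle 0.145, Tyrobp 16.8, Vdr 2.83, and those in NKT-3 library 5 included Ccr9 3.72, Cd24a 1.74, Cd4 2.42, Cd79b 13.5, Cpa3 8.08, Fn1 0.697, Fos 15.9, Il17f 1.6, Kit 0.76, Rgs1 290. In NKT-1 library 3 they were Car2 0.0299, Col1a2 0.0575, Cpa3 2.54, Ctsg 1.25, Cxcl12 0.209, Ifitm1 5.97, Klra6 2.62, Mpo 1.78, Prss34 68.1. The remaining libraries far from their groups were NKT-1 library 5 (Cd4 30.1), DN1eP library 2 (Cd6 34.9, Fn1 0.561, Il13 1.82, Lif 0.253), DN1eP library 3 (Cish 49.1), NKT-3 library 1 (Col1a1 0.557), NKT-2 library 1 (Col1a2 0.015, Cxcl12 0.133, Il10 0.269), NKT-3 library 4 (Col1a2 0.00965, Ctsg 0.0597, Mpo 0.0407, Prss34 2.5), NKT-2 library 5 (Ctsg 0.0609, Mpo 0.187, Ncr1 0.0772, Prss34 2.35), DN1eP-NKT library 4 (Egr2 0.826, Lmo4 19.4), DN1eP-NKT library 2 (Il2ra 92.7), NKT-1 library 4 (Itga1 0.116, Klra5 14.8, Klra9 12, Klri2 1.3), NKT-3 library 6 (Lif 0.217), NKT-1 library 1 (Lztfl1 22.8, Tnfrsf9 9.41), NKT-2 library 7 (Ptpn22 74.4), NKT-3 library 3 (Rln3 0), NKT-1 library 2 (Rpl34 16.6, M fragments 1.21).

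The first pattern weighed is the split of the libraries into 2 sets. A preparation that takes up genes by length or GC content may be part of its source, since the difference between sets had a Spearman correlation of 0.365 with gene length and 0.238 with GC content over 10523 genes. Sequencing depth as the source is argued against by slopes of 0.163, 0.0776, 0.130 and 0.0553 of the deep minus shallow difference on the set difference, all below the bound set beforehand. Each slope rests on 1 deep library. In thymic cells depth nearly followed the sets, with all lower-median libraries at 19.9 to 28.0 M fragments and most higher-median ones at 1.12 to 2.98 M. But DN1eP libraries 2 to 4, of the lower-median set, were at 1.03 to 1.84 M, and the higher-median NKT-1 library 1 was at 15.4 M. Cell stage is argued against as the source of the split, since 3 of 3 thymic stages hold libraries of both sets. The 2 kits stay an open explanation, since the labels do not give them per library, and no biological explanation other than cell stage was tested.

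The second pattern is B cell, myeloid and erythroid transcripts in NKT-2 library 6 and NKT-3 library 5. NKT-2 library 6 held Cd74 at 1460 FPKM, Cd79a at 42.3, Ly6d at 87.6 and Lyz2 at 60.4, and NKT-3 library 5 held Cd74 at 337, Hba-a1 at 315 and Cd79a at 15.4. RNA from B cells may be the source in NKT-2 library 6, where 7 of 8 tested B cell genes lay above each other NKT-2 library, while 5 of 8 in NKT-3 library 5 leaves B cell RNA open there. More NKT17 cells may also be in NKT-2 library 6, with 13 of 19 genes above each other library, which just meets the number set for that test. Blk is among the 13, at 143 FPKM against 7.43 to 40.7, and without it the number would not be met. Among stage 3 libraries Blk was also highest in NKT-3 library 5, at 9.49, so it may not mark NKT17 cells here. The gate on the Vα14Jα18 receptor is meant to leave out B cells, but its purity was not measured here. Blk is in both the NKT17 and the gamma-delta T cell lists.

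The third pattern is NKT1, cytotoxic and NKT17 transcripts in DN1eP. NK cells as most of the sort are argued against by Cd3e, whose mean was 110% of that in the lower-median stage 3 libraries. Stage 3 NKT cells carried over are argued against as the whole source by 5 genes higher in DN1eP than in those libraries (Ncr1, Ccl5, Ccl4, Ccl3 and Eomes), which only just meets the number of 5 set before that result was seen, though after the library sets were found, and a smaller share stays open. Gamma-delta T cells cannot be told apart from the other explanations, since 3 of Sox13, Cd163l1, 5830411N06Rik and Etv5 were higher in DN1eP, between the bounds set. The DN1eP gate, lineage-negative and without the Vα14Jα18 receptor, is meant to leave out NKT cells. The purity of the sort was not measured here, and Cd3e was at 1120 to 1540 FPKM in DN1eP. The markers behind lineage-negative, which decide whether the gate also leaves out NK and gamma-delta T cells, are not given in the sources used here. A program of the precursors themselves stays open as untested.

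Other splits of the same libraries were counted for each comparison. For DN1eP-NKT minus DN1eP only the real split gave as many genes (1 of 35 splits, the real 6136 and the highest other 312), but that split is also the split between the 2 library sets. In the other comparisons the share of splits with as many genes was under 0.05, though some other splits gave more genes. It was 4 of 100 for the NKT mean minus DN1eP (3264 and 4158) and 4 of 100 for stage 2 minus stage 1 (27 and 6525). For stage 3 minus stage 2 it was 3 of 100 (1460 and 6224). For DN1eP-NKT it was 3 of 100 against stage 1 (2326 and 3996), 2 of 100 against stage 2 (1637 and 3341) and 2 of 100 against stage 3 (2077 and 4085). The splits with more genes point to a structure of the samples, as the highest of them placed 77.3%, 91.7%, 92.3%, 88.9%, 90.9% and 90.0% of libraries by library set. With library set as a term and splits within sets, only the real split gave as many genes for the NKT mean minus DN1eP (1 of 100, 4112 and 50). The same held for stage 2 minus stage 1 (1 of 100, 93 and 10) and stage 3 minus stage 2 (1 of 100, 3438 and 2188). It also held for DN1eP-NKT minus stage 2 (1 of 70, 2406 and 1186) and stage 3 (1 of 35, 3054 and 239). For DN1eP-NKT minus stage 1 the 15 splits are too few for a share under 0.05 (1 of 15, the real 2528 and the highest other 131). None of these shares was adjusted over the comparisons, and the labels do not say whether replicates are independent, so chance is not excluded.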

How the results depend on the processing

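Library set as a term, fits within 1 set, NKT-2 library 6 and NKT-3 library 5 left out, stage means of the higher-median libraries and the split controls with library set were chosen only after the result was seen, and the others were planned.

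Array weights gave 7059 for the NKT mean minus DN1eP, 7407 for stage 2 minus stage 1, 3472 for stage 3 minus stage 2, and 8570, 3220 and 4048 for DN1eP-NKT minus stages 1, 2 and 3. The weights were lowest for the higher-median libraries in stage 1 and for the lower-median libraries in stages 2 and 3. The array-weight counts that involve stage 1 therefore take in the difference between sets. Against a 2-fold change, limma treat left 886 for DN1eP-NKT minus DN1eP, then 184, 1, 277, 414, 353 and 488 in the same order, by its construction. With library set as a term the counts were 3748 for DN1eP-NKT minus DN1eP, 93 for stage 2 minus stage 1 and 3438 for stage 3 minus stage 2. The higher-median libraries alone gave 3269 for stage 3 minus stage 2, 2837 for DN1eP-NKT minus stage 2 and 3463 for DN1eP-NKT minus stage 3, and the lower-median libraries alone 830 for stage 3 minus stage 2 and 15 for stage 2 minus stage 1. For stage 2 minus stage 1 quantile normalization gave 16 and only the compared groups 1. A filter of 5 FPKM gave 1060 for DN1eP-NKT minus stage 2, with fewer genes tested. Unless the construction or the weights show it, the cause was not tested.

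As a paired check, the replicate numbers were used as a replicate block, which gave 6897 for the NKT mean minus DN1eP (4633 higher and 2264 lower) and counts within 1.5 times the main ones elsewhere. Whether replicate numbers pair the libraries cannot be told. Of 26 libraries, 6 correlated best with a library of their own number. In deviations from the group mean, pairs of the same number had a mean correlation of 0.137, against -0.0284 for other pairs. Pairs of the same library set had 0.273 and pairs of different sets -0.243. In each thymic stage the lower replicate numbers are higher-median libraries and the higher numbers lower-median ones. The block therefore also takes up part of the difference between sets. Without 1 library in turn, counts ranged from 5282 to 5637 for DN1eP-NKT minus DN1eP, 2033 to 3753 for the NKT mean minus DN1eP, 7 to 28 for stage 2 minus stage 1, 1280 to 1510 for stage 3 minus stage 2, and 1579 to 3641, 1204 to 1752 and 1545 to 2318 for DN1eP-NKT minus stages 1, 2 and 3. The 7 came without NKT-1 library 3 and the 3641 without NKT-1 library 2.

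Gene list tests called 83 list and comparison pairs, and 37 with an estimated correlation. The correlation of the shared effect was 0.70 with library set as a term, 0.674 with split controls and 0.524 with both. The lead of stage 2 over stage 3 in rank correlation was 0.0153 with a filter of 5 FPKM and 0.0157 with stage means of the higher-median libraries, and ranged from 0.00679 to 0.0105 without 1 DN1eP-NKT library.

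Genes whose log2 fold change took the other sign mostly had no call as reported. With array weights these were Cd44 in DN1eP-NKT minus DN1eP (0.20), Cd5 in NKT-2 minus NKT-1 (0.48), Zbtb16 in NKT-2 minus NKT-1 (1.62, adjusted p = 0.000886, a call), Egr2 in NKT-2 minus NKT-1 (0.46), Cd44 in DN1eP-NKT minus NKT-2 (-0.054), Cd24a in DN1eP-NKT minus NKT-2 (0.16). In NKT-2 minus NKT-1 these weights mix stage with library set. With quantile normalization these were Zbtb16 in DN1eP-NKT minus DN1eP (-0.35), Cd27 in NKT-3 minus NKT-2 (0.15), Cd24a in DN1eP-NKT minus NKT-1 (-0.19), Cd44 in DN1eP-NKT minus NKT-2 (-0.092), Cd24a in DN1eP-NKT minus NKT-3 (-0.033). With library set as a term these were Zbtb16 in DN1eP-NKT minus DN1eP (-2.15, adjusted p = 1.78e-05, a call), Tbx21 in DN1eP-NKT minus DN1eP (-0.59), Gata3 in DN1eP-NKT minus DN1eP (0.041), Tbx21 in NKT mean minus DN1eP (-0.39), Cd44 in DN1eP-NKT minus NKT-2 (-0.21), Cxcr3 in DN1eP-NKT minus NKT-2 (0.15). With the lower-median libraries alone these were Tbx21 in NKT mean minus DN1eP (-0.39), Cd27 in NKT-3 minus NKT-2 (0.12). With the higher-median libraries alone these were Cd24a in NKT-2 minus NKT-1 (-0.13), Cd27 in NKT-2 minus NKT-1 (0.021), Slamf6 in NKT-2 minus NKT-1 (0.015), Cd24a in DN1eP-NKT minus NKT-1 (-0.13), Cd44 in DN1eP-NKT minus NKT-2 (-0.22), Tbx21 in DN1eP-NKT minus NKT-2 (-0.028). With replicate block these were Zbtb16 in NKT-2 minus NKT-1 (0.47), Egr2 in NKT-2 minus NKT-1 (0.036), Cd27 in NKT-3 minus NKT-2 (0.022), Cd44 in DN1eP-NKT minus NKT-2 (-0.25), Cxcr3 in DN1eP-NKT minus NKT-2 (0.042). With NKT-2 library 6 and NKT-3 library 5 left out these were Zbtb16 in NKT-2 minus NKT-1 (0.079), Egr2 in NKT-2 minus NKT-1 (0.053), Cd24a in DN1eP-NKT minus NKT-2 (0.084). With upper-quartile scaling these were Cd27 in NKT-3 minus NKT-2 (0.15), Cd44 in DN1eP-NKT minus NKT-2 (-0.18). Tbx21 in DN1eP-NKT minus DN1eP is the gene among them that had been called as reported.

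Leaving out 1 library moved several genes across 0, among them with ranges of -0.033 to 0.20 for Cd24a in DN1eP-NKT minus NKT-1, -0.39 to 0.084 for Cd24a in DN1eP-NKT minus NKT-2, -0.14 to 0.072 for Cd27 in NKT-3 minus NKT-2, -0.20 to 0.21 for Cd44 in DN1eP-NKT minus DN1eP, -0.018 to 0.28 for Cd44 in DN1eP-NKT minus NKT-2, -0.24 to 0.10 for Cd5 in DN1eP-NKT minus DN1eP, -0.40 to 0.21 for Egr2 in DN1eP-NKT minus DN1eP, -0.46 to 0.041 for Egr2 in DN1eP-NKT minus NKT-3, -0.26 to 0.053 for Egr2 in NKT-2 minus NKT-1, -0.31 to 0.29 for Tbx21 in DN1eP-NKT minus NKT-3, -0.56 to 0.15 for Zbtb16 in DN1eP-NKT minus NKT-3, -0.57 to 0.28 for Zbtb16 in NKT-2 minus NKT-1. Depth limits the libraries near 1.03 M fragments, where the deposited interval spans up to 23.7%.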

Other observations

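The values here come from no planned test. Ncr1 stood at 36.2 FPKM in DN1eP-NKT library 1 against 1.17 to 4.23 in the other 3. The DN1eP sort gate asks for cells without Ly108, and Slamf6 was at 8.24 ± 6.02 FPKM in DN1eP (n = 4). Cd4 was at 0.843 FPKM in NKT-2 library 6 and at 36.7 to 87.3 in the other 6 NKT-2 libraries.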
